A study of Mus musculus with 32 samples.

How the data were processed

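The series holds 32 mouse samples in 12 groups, all from striatum of C57BL/6 animals aged 3 to 6 months, per the labels. In 3 models a floxed Mettl14 gene (fM14 in the labels) was deleted: in striatonigral neurons (D1R_KO against D1R_WT), in striatopallidal neurons (A2AR_KO against A2AR_WT), or in all neurons of adult mice through a virus (Viral_Cre against Viral_GFP). Each model has 6 RNA-seq libraries, 3 per group. The m6A-RNA-seq samples number 14: the A2AR and Viral models have 3 libraries per group, each with its own RNA-seq library as input, and the D1R model has 1 library per group, whose input is the 3 RNA-seq libraries of that group, per the labels. The labels do not say whether replicates are separate animals or pools, so a p-value measures the spread between these samples, which may be technical. All 3 Viral_Cre libraries held both Xist, a transcript of females (26.2, 35.9 and 12.3 RPKM), and Y-linked genes (means 3.64, 2.44 and 6.95). Pools of both sexes would give this. Both also appeared in Viral_GFP 1, D1R_WT 1, D1R_KO 1, A2AR_WT 3, A2AR_KO 1 and A2AR_KO 2. Viral_GFP 2 (Xist 61.4, Y-linked 0.0258) and Viral_GFP 3 (0.0334 and 7.54) did not hold both.

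RNA was extracted with Trizol, poly(A) RNA was purified with Dynabeads and libraries were made with an Illumina TruSeq kit, per the labels' protocols. Reads were aligned to mm10 with TopHat2 2.0, and TopHat is also listed, per the submitters' processing notes. The program that counted reads, the peak caller and the peak threshold are not given in the sources used here. Per the file headers, the authors' gene tables hold 1 RPKM value (reads scaled to gene length and library total) per gene symbol and library. Per the file headers, the authors' peak lists hold a log2 m6A enrichment score per peak, the antibody library over its input, with the RefSeq transcript, the start and end on that transcript and the part of the transcript. In the A2AR and Viral models each peak has a score for every library of both groups. In the D1R model the deposited lists give 1 score per peak and the log2 ratio of the groups. Each model has 1 peak list per group, so replicates were not called separately. The authors' peak scores are used here to describe, rank and compare peaks within a model.

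Depth is unknown because only RPKM values were used. Low values were checked for steps that would give whole reads, and none appeared: at most 7.28% of genes shared the commonest ratio between a library and the first control of its table. Genes above 0 numbered between 17445 and 18382 per library. The RPKM sum of a library ranged from 523217 to 819838 in D1R, from 936738 to 1205140 in A2AR and from 805293 to 983349 in Viral. Short RNAs held between 15.3% and 60.6% of a library's sum. The 3 tables were normalized separately, so tests were made within a table, and levels are not compared across tables. Correlations between libraries of a table, over the tested genes, ranged from 0.913 to 0.955, and 0 pairs of libraries held identical values.

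Gene symbols were matched to the GRCm38.p6 RefSeq table, the assembly that mm10 represents, for coordinates: 23738 of 23842 symbols matched in D1R and 23762 of 26440 in both A2AR and Viral. In each gene table, 27 entries carried a symbol that a spreadsheet had turned into a date, and these were left out.

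Expression was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided) on log2(RPKM + 0.5), in the 6 libraries of a model, for genes with a mean RPKM of at least 0.5. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are deletion minus control on the log2(RPKM + 0.5) scale, which understates the change of genes with low values, and ± is the standard error from limma unless SD is named. Differences between models were tested in 1 limma fit over the 18 RNA-seq libraries with 6 group means, as the contrast of 2 within-model effects. On data simulated from these libraries, the fit of 6 libraries recovered 83, 81 and 82 of 100 genes changed by 1 on the log2 scale in D1R, A2AR and Viral (15024, 15076 and 15168 genes), and 99, 100 and 96 of 100 changed by 2, with 4, 5 and 5 false calls. Changes were planted only in genes with a mean log2(RPKM + 0.5) over 2 that are not short RNAs, with noise drawn independently. Many planted changes also ease the adjusted threshold, so these shares do not carry over to all tested genes. The 18-library fit recovered 97, 93 and 95 of 100 at a change of 1 (14533 genes) but made 69, 38 and 51 false calls, so its counts of called genes are too high in such data. These false calls came beside 100 planted changes of 1 and 100 of 2 per model, so they do not count the false calls in the real data. It was kept as an alternative.

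Gene lists, 27 in all, cover markers of the striatal neuron types and of the other cell types a dissection can hold, neuronal signalling and activity, immune and stress responses, protein synthesis, respiration, the m6A machinery and sex-linked genes. The list of mitochondrially encoded genes had 0 measured members, and the other 26 were tested with camera of limma at a preset inter-gene correlation of 0.01, again with the correlation estimated, and with fry. Adjusted p-values of lists are Benjamini-Hochberg values over the 26 lists of a model. Some lists share members. A list that is past the threshold only at the preset correlation is said to be higher or lower at that correlation.

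Peaks of the 2 groups of a model were compared by overlap of at least 1 bp on the same transcript with GenomicRanges 1.54.1, and shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. Scores per library in A2AR and Viral were tested with limma over the control list plus the deletion peaks that overlap no control peak. On simulated shifts this test recovered 0 of 100 peaks shifted by −1 and 18 of 100 shifted by −2 in A2AR (34430 peaks), and 2 and 38 of 100 in Viral (31072 peaks), with 1 false call in each. The D1R lists have no replicates, so they carry no test. For m6A and expression, genes with a peak were compared with genes without, and genes whose control peaks all lack a deletion overlap (lost) with genes that kept 1 or more. Both are differences of mean log2 fold changes, with two-sided permutation tests of 100000 resamples. The log2 ratio of the highest peak per gene was correlated with the expression fold change across genes. These 9 tests form 1 family for Benjamini-Hochberg adjustment.

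The groups, the tests, the gene lists, the rule for named genes and most alternative settings were chosen before the data were examined. The rule names Mettl14 first, then up to 10 called genes per direction whose groups do not overlap, then, where fewer than 5 pass, the 5 with the smallest p as not past the test, and 2 to 4 members of a described list with the smallest p. Predicted genes (Gm, Rik) and short RNAs count but do not fill the 10. For m6A it names the 5 highest peaks of each list without an overlap and peaks in Mettl14 and the named genes. Genes named from the 18-library fit follow the same rule on that fit. Alternatives fixed beforehand were pseudocounts of 0.1 and 1, no filter and a mean RPKM of at least 1, quantile or median scaling, the 18-library fit, no trend, a replicate block, leaving out each library (for called genes and differences between models), an overlap of 50%, top peaks only, a mean RPKM of at least 5, matching on expression in 20 bins and the mean peak per gene. Alternatives chosen after seeing the data were robust eBayes, leaving out short RNAs, a Y-linked covariate, removing the trend of expression on gene span (lowess, span 0.3) a term for, or the omission of, the first D1R replicates, and leaving out each library for lists, m6A peaks and m6A and expression. The other values came from Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and the plots from matplotlib 3.10.9.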

Results

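Striatal RNA was sequenced in 3 mouse models of Mettl14 deletion, with 3 deletion and 3 control libraries in each. Mettl14 encodes the RNA-binding partner of Mettl3 in the complex that writes N6-methyladenosine (m6A) into mRNA. The D1R model deletes it in striatonigral neurons, which express the dopamine D1 receptor, the A2AR model in striatopallidal neurons, which express the adenosine A2a and dopamine D2 receptors, and the Viral model in all neurons of the adult striatum. m6A-RNA-seq libraries, in which RNA fragments bound by an m6A antibody are sequenced, number 3 per group in the A2AR and Viral models and 1 per group in the D1R model. The series text names the relation between changes in mRNA and changes in m6A enrichment as the question of the design. All striatal cells contribute to each library, so the values are for the tissue and not for the targeted neurons.

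Mettl14 itself (chromosome 3, 123368295 to 123385990, mm10) showed small differences in whole-gene RPKM. In D1R it was listed at 7.71, 5.31 and 5.95 RPKM in the controls and at 5.28, 4.25 and 4.59 in the deletion libraries, a log2 fold change of −0.38 ± 0.15 (limma, n = 3 per group, adjusted p = 0.439). The fold change was −0.04 ± 0.09 in A2AR (adjusted p = 0.921 by limma) and −0.09 ± 0.11 in Viral (adjusted p = 0.937 by limma), with overlapping groups in both. Reads from undeleted cells and from exons outside the deleted part count toward these values, and the labels do not name the deleted exons, so RPKM is a weak check of the deletion.

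**Figure D1:**
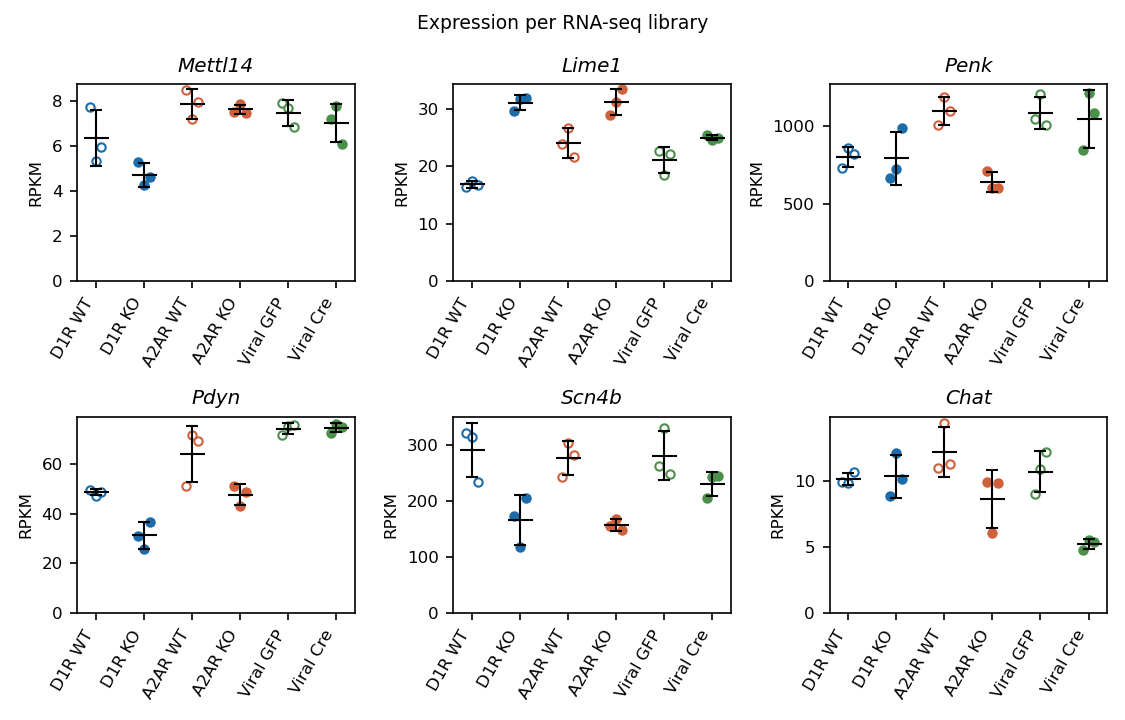
RPKM (y axis, linear) of 6 genes in the 18 RNA-seq libraries; each point is 1 library, open for control and filled for deletion, and bars give the mean ± SD of 3 libraries. Lime1 lies at 17.5 or below in D1R_WT and at 29.6 or above in D1R_KO, while Mettl14 overlaps between the groups of A2AR and Viral.

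Deletion in striatonigral neurons was first compared with its control to find which striatal mRNAs differ. Genes of striatal projection neurons were lower as a group in D1R_KO, with 28 of 30 measured members lower and a median log2 fold change of −0.36, and cytosolic ribosomal protein genes were higher, with all 75 measured members higher and a median of 0.28. Both lists passed camera at the preset correlation only (adjusted p = 0.656 and adjusted p = 0.630 with an estimated correlation). Projection neuron list means were −0.33, −0.67 and −0.07 in D1R_KO against 0.07, 0.07 and −0.14 in D1R_WT, so the groups overlap and the lower mean rests on D1R_KO 1 and 2. Immediate early genes, which neurons switch on with activity, were lower in 20 of 26 members, and myelin genes were lower in 20 of 21, with adjusted p = 0.630 and adjusted p = 0.656 with an estimated correlation. Among single genes, Tgm7, a transglutaminase, and Lime1, an adaptor of Src-family kinases in lymphocytes, rose.

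Of 15024 genes tested, limma called 3 higher and 2 lower in D1R_KO, and 1632 had an unadjusted p under 0.05. Of the 3 higher calls, 1 is not used here. Tgm7 (chromosome 2, 121093498 to 121116396) rose by 1.86 ± 0.13, from at most 0.136 RPKM to 1.73, 1.67 and 1.73 (limma, adjusted p = 0.0165). Lime1 (chromosome 2, 181381235 to 181383628) rose by 0.86 ± 0.07, from 16.4, 17.5 and 16.7 to 29.6, 31.7 and 32.0 RPKM (limma, adjusted p = 0.0244). The 2 lower calls are short RNAs. Snora30, a guide RNA for pseudouridylation, was listed at 31.0, 25.2 and 41.6 RPKM in the controls and at 0 in each deletion library (limma, adjusted p = 0.000235). Mir433, a microRNA precursor, was listed at 22.1, 52.2 and 65.3 in the controls and at 0.000573 or less in the deletion libraries (limma, adjusted p = 0.00846). Neither was called in the 18-library fit (limma adjusted p of 0.293 and 0.203), and values of exactly 0 for a short RNA in poly(A) libraries can come from the quantification, which the deposited values cannot tell from a change. Another short RNA, Snord33, was listed at 0 in 1 of the 6 D1R libraries and at 218 or more in the other 5. The groups did not overlap in 16.9% of genes, where chance gives 10%.

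Neuronal genes made up most of the lists that were lower in D1R_KO at the preset correlation. The shared projection neuron list gave a camera adjusted p of 1.39e-06 (adjusted p = 0.656 with an estimated correlation). Its members with the smallest p were Ryr1, an intracellular calcium release channel (−1.24 ± 0.13, adjusted p = 0.0600 by limma), Dgkb, a diacylglycerol kinase (−0.68 ± 0.18), Scn4b, a sodium channel beta subunit (−0.83 ± 0.23), and Pde1b, a calcium-dependent phosphodiesterase (−0.54 ± 0.18). All 9 measured D1 markers were lower, with a median of −0.19 (camera adjusted p = 0.00399, and adjusted p = 0.630 with an estimated correlation). Among them Pdyn, the dynorphin precursor, gave −0.64 ± 0.13 and Tac1, the substance P precursor, −0.69 ± 0.17. D2 markers had a median of −0.05 (camera adjusted p = 0.638). Dopamine and cAMP signalling genes had a median of −0.19 with 27 of 33 lower, Pde1b and Rgs2 (−0.36 ± 0.12) among them (camera adjusted p = 0.00613, and adjusted p = 0.656 with an estimated correlation). Immediate early genes had a median of −0.29 (camera adjusted p = 0.000716, and adjusted p = 0.630 with an estimated correlation), with Egr1 at −0.55 ± 0.07, Egr2 at −0.84 ± 0.18, Nr4a2 at −0.75 ± 0.20 and the scaffold gene Homer1 at −0.49 ± 0.15. Synaptic genes (median −0.09, 34 of 49 lower) and voltage-gated ion channels (median −0.10, 42 of 63 lower) each had a camera adjusted p of 0.0363, with adjusted p = 0.656 and adjusted p = 0.630 with an estimated correlation. D1R fold changes correlated with gene span (Spearman −0.208), and with that trend removed the synaptic and ion channel lists had camera adjusted p-values of 0.699 and 0.373. Rims1, an active zone protein, gave −0.40 ± 0.07, and Cacna1e, a calcium channel, −0.34 ± 0.09.

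Lists of other cell types also passed camera in D1R at the preset correlation, though of the 6 lists here only the endothelial and ribosomal list means did not overlap between D1R_KO and D1R_WT. Oligodendrocyte and myelin genes had a median of −0.22 (camera adjusted p = 0.000649, and adjusted p = 0.656 with an estimated correlation), with Ugt8a, which makes a myelin lipid, at −0.40 ± 0.13 and Tspan2 at −0.31 ± 0.10. Their list means were −0.23, −0.41 and 0.06 in D1R_KO. Endothelial and mural markers had a median of −0.10 (camera adjusted p = 0.0363, and adjusted p = 0.652 with an estimated correlation), with Cldn5, of the tight junctions, at −0.38 ± 0.10 and the pericyte gene Rgs5 at −0.25 ± 0.10. Choroid plexus and ependymal markers, genes of tissue next to the striatum, had a median of 0.97 (camera adjusted p = 0.00504, and adjusted p = 0.656 with an estimated correlation). Kl, which encodes klotho, was at 5.72, 2.27 and 12.5 RPKM in D1R_KO against 1.26, 1.65 and 1.32 in D1R_WT, and Sostdc1 gave 1.10 ± 0.26 and Prlr 1.13 ± 0.29. Choroid plexus list means were 0.82, −0.07 and 1.68 in D1R_KO, so D1R_KO 2 lay within the controls. Blood genes had a median of 0.37 (camera adjusted p = 0.0200, and adjusted p = 0.630 with an estimated correlation), with the globin gene Hbb-b1 at 1.21 ± 0.33 and Alas2, of haem synthesis, at 0.41 ± 0.17. Blood list means were −0.64, 0.58 and 0.84 in D1R_KO against 0.43, −0.84 and 0.41 in D1R_WT. Ribosomal proteins gave a camera adjusted p of 8.62e-19 (adjusted p = 0.630 with an estimated correlation), with Rps15 at 0.47 ± 0.11, Rpl37 at 0.40 ± 0.09 and Rpl27a at 0.39 ± 0.09. Nuclear respiratory chain genes had a median of 0.04 with 49 of 74 higher (camera adjusted p = 0.0215, and adjusted p = 0.680 with an estimated correlation), with Ndufa8 at 0.29 ± 0.11 and Uqcrq at 0.35 ± 0.14. With the span trend removed the blood and respiratory chain lists had camera adjusted p-values of 0.132 and 0.358.

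Limma called 0 members of these 12 lists when adjusted over all genes. Adjusted over the list alone it called 2 D1 markers, 2 immediate early genes and 1 projection neuron gene, all lower, and 0 in the other 9 lists. At an unadjusted p under 0.05 there were 9 lower projection neuron genes, 6 lower and 1 higher immediate early genes, 3 lower D1 markers and 20 higher ribosomal protein genes. The m6A machinery list had a median of −0.05, a mean of 0.03 and a camera direction upwards (adjusted p = 0.403), with the m6A readers Ythdf1 and Ythdf2 at 0.34 ± 0.09 and 0.42 ± 0.12 and Fmr1 at −0.25 ± 0.09. Of the other lists not past the threshold, thalamic, septal and pallidal markers had a median of −0.23, interferon genes 0.10, interneuron markers −0.09, reactive glia 0.08, precursor markers −0.07, microglia −0.03, unfolded protein genes 0.02 and p53 targets 0.01. Astrocyte markers and neuropeptides lay within 0.01 of 0. Cortical markers had a median of −0.06, a mean of 0.0041 and a camera direction downwards, and sex-linked genes a median of −0.09 with a camera direction upwards. Camera adjusted p-values of these lists were between 0.112 and 0.941. The Tgm7 and Lime1 calls were each lost with a Y-linked covariate, with a replicate block, without both replicate 1 libraries and without some single libraries, Lime1 without any 1 of the 6. D1R_WT 1 and D1R_KO 1 stand apart from the other 4 libraries, with RPKM sums of 819838 and 817746 against 523217 to 564865. Without both, projection neuron, D1 marker, immediate early, oligodendrocyte and ribosomal lists stayed past the camera threshold.

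A single limma fit over the 18 libraries called 160 genes in D1R, 129 higher and 31 lower, in each of which the groups did not overlap, and 3 of the 160 were also called in the fit of 6 libraries. Among the highest were Aspdh, an aspartate dehydrogenase-like gene (2.50 ± 0.36), Ccl21b, a chemokine (1.98 ± 0.30), Fdx1l, a ferredoxin of iron-sulfur cluster assembly (1.21 ± 0.15), and Fst, follistatin (1.05 ± 0.20). Among the lowest were Ryr1 (−1.24 ± 0.21), Ano2, a calcium-activated chloride channel (−0.96 ± 0.21), Krt10, a keratin (−0.90 ± 0.18), Scn4b and Pdyn (−0.64 ± 0.12). Adjusted p-values of these 9 genes in the 18-library limma fit ranged from 0.000844 to 0.0343. This fit made 69 false calls for D1R in simulated data with planted changes.

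In the A2AR model, which asks the same of striatopallidal neurons, the list with the smallest camera p was that of shared projection neuron genes. Of its 30 measured members 29 were lower in A2AR_KO, with a median log2 fold change of −0.47, and 23 fell when adjusted over the list alone. Penk, the enkephalin precursor of striatopallidal neurons, was at 1010, 1194 and 1102 RPKM in A2AR_WT and at 712, 600 and 600 in A2AR_KO. Ribosomal protein, cortical neuron and interferon genes were higher at the preset correlation. These lists and the projection neuron list each had an adjusted p = 0.457 with an estimated correlation, and the library means of the cortical and interferon lists overlap between A2AR_KO and A2AR_WT.

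Of 15076 genes tested, limma called 1 gene, Snord55, a guide RNA for 2′-O-methylation, which was listed at 0 in all 3 controls and at 243, 163 and 181 RPKM in A2AR_KO (adjusted p = 2.42e-06). As for the short RNAs in D1R, the quantification can give such zeros, so the Snord55 call is not read as a change in level. At an unadjusted p under 0.05 there were 1379 genes, and the groups did not overlap in 15.4% of genes against 10% by chance. The next smallest p-values, not past the test, included those of Aspdh (1.78 ± 0.18), with a limma adjusted p of 0.165. Others were Gucy1a3, a subunit of the nitric oxide receptor (−0.55 ± 0.07), and S100a10, which carries membrane proteins to the cell surface (0.94 ± 0.11), both with a limma adjusted p of 0.188.

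Shared projection neuron genes gave a camera adjusted p of 3.66e-26 (adjusted p = 0.457 with an estimated correlation), and limma called 0 of the 30 over all genes. Scn4b gave −0.81 ± 0.10, Actn2, an actin crosslinker of the postsynapse, −0.51 ± 0.07, Pde10a, a striatal phosphodiesterase, −0.66 ± 0.10, and Rxrg, a retinoid receptor, −0.59 ± 0.09, with limma adjusted p-values from 0.188 to 0.251. D2 markers had a median of −0.20 (camera adjusted p = 0.000549, and adjusted p = 0.457 with an estimated correlation), and 3 of 9 fell when adjusted over the list alone. Penk (chromosome 4, 4133536 to 4138815) gave −0.79 ± 0.11 with a limma adjusted p of 0.189 over all genes, the orphan receptor Gpr52 −0.67 ± 0.15 and the D2 receptor gene Drd2 −0.50 ± 0.13. D1 markers had a median of −0.25 (camera adjusted p = 0.00333, and adjusted p = 0.457 with an estimated correlation), with the muscarinic receptor Chrm4 at −0.34 ± 0.08, Drd1 at −0.43 ± 0.13 and Pdyn at −0.41 ± 0.14. Of the D1 markers, 1 of 9 fell when adjusted over the list alone. Dopamine and cAMP signalling genes had a median of −0.24 with 15 of 33 lower when adjusted over the list alone (camera adjusted p = 2.71e-13, and adjusted p = 0.457 with an estimated correlation). Pde1b lay at −0.54 ± 0.09, the G protein subunit Gng7 at −0.54 ± 0.10 and the cyclase Adcy5 at −0.46 ± 0.09. Voltage-gated ion channels had a median of −0.09 (camera adjusted p = 0.000520, and adjusted p = 0.457 with an estimated correlation), with the potassium channel gene Kcna4 at −0.63 ± 0.08 and Kcnab1 at −0.50 ± 0.10.

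Higher lists in A2AR_KO began with the ribosomal proteins, at a median of 0.22 with 72 of 76 higher (camera adjusted p = 1.75e-20, and adjusted p = 0.457 with an estimated correlation), Rps15 at 0.36 ± 0.09 and Fau at 0.32 ± 0.08. Nuclear respiratory chain genes had a median of 0.09 with 61 of 73 higher (camera adjusted p = 7.15e-07, and adjusted p = 0.493 with an estimated correlation), Ndufb8 of complex I at 0.27 ± 0.07 and Cox4i1 of complex IV at 0.26 ± 0.08. Interferon and antigen presentation genes had a median of 0.33 with 23 of 26 higher (camera adjusted p = 5.52e-05, and adjusted p = 0.457 with an estimated correlation), the class II gene H2-Aa at 0.75 ± 0.25 and Isg15 at 0.84 ± 0.31. Cortical excitatory neuron markers had a median of 0.32 with 13 of 14 higher (camera adjusted p = 0.000161, and adjusted p = 0.457 with an estimated correlation), Nrn1 at 0.48 ± 0.13 and the transcription factor Neurod6 at 0.39 ± 0.13. Cortical list means were 0.01, 0.38 and 0.51 in A2AR_KO against 0.22, −0.19 and −0.02 in A2AR_WT, so A2AR_KO 1 lay within the controls. Sex-linked genes had a median of −1.69 (camera adjusted p = 0.0553). The labels give no sex, and sex-linked genes differed between libraries of the same A2AR group as well as between the groups, so the groups were not matched for them. Xist was at 0.0366, 0.0219 and 27.5 RPKM in A2AR_WT and at 33.7, 17.7 and 39.2 in A2AR_KO. With the level of Y-linked genes as a covariate, 775 A2AR genes had an unadjusted limma p under 0.05, against 1379 without it. The covariate goes with the groups, with Y-linked means of 9.20, 7.65 and 3.35 RPKM in A2AR_WT and 1.37, 4.75 and 0.00781 in A2AR_KO. This count can thus fall whether or not sex contributes. Since the groups were not matched for sex-linked genes, differences between them can still hold a part that goes with sex. Of the other lists not past the threshold, thalamic, septal and pallidal markers had a median of 0.38, interneuron markers −0.23, with Slc5a7 at −0.62 ± 0.11 and Vip at 0.91 ± 0.17. Immediate early genes had a median of −0.11, neuropeptides −0.13, precursor markers −0.10, endothelial markers 0.10, microglia markers −0.08, reactive glia 0.08 and blood genes 0.15. Astrocyte, myelin, synaptic, unfolded protein, p53 and m6A machinery lists lay between −0.04 and 0.04. Choroid plexus markers had a median of −0.06, a mean of 0.11 and a camera direction upwards. Camera adjusted p-values of these lists were between 0.0521 and 0.915.

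The 18-library limma fit called 10 genes in A2AR, 8 higher and 2 lower, 0 of them also called by the fit of 6 libraries, and made 38 false calls in simulated A2AR data with planted changes. Besides S100a10 they include Ccl17, a chemokine (1.85 ± 0.30), Col20a1, a collagen (1.32 ± 0.17), Vsig2, an immunoglobulin-domain protein (1.21 ± 0.14), and Fst (1.16 ± 0.20) as higher. As lower they include Pcdhga9, a clustered protocadherin (−0.71 ± 0.12), and Sorcs2, a neurotrophin co-receptor (−0.46 ± 0.08). Uts2, a vasoactive peptide gene, was listed at 0 in all controls and at 2.13, 1.46 and 0.957 RPKM in A2AR_KO. Adjusted p-values of these 8 genes in that limma fit were between 0.00303 and 0.0490. Leaving out 1 library moved the count of called genes from 1 to as many as 14 (without A2AR_WT 3), so the count rests on single libraries.

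**Figure D2:**
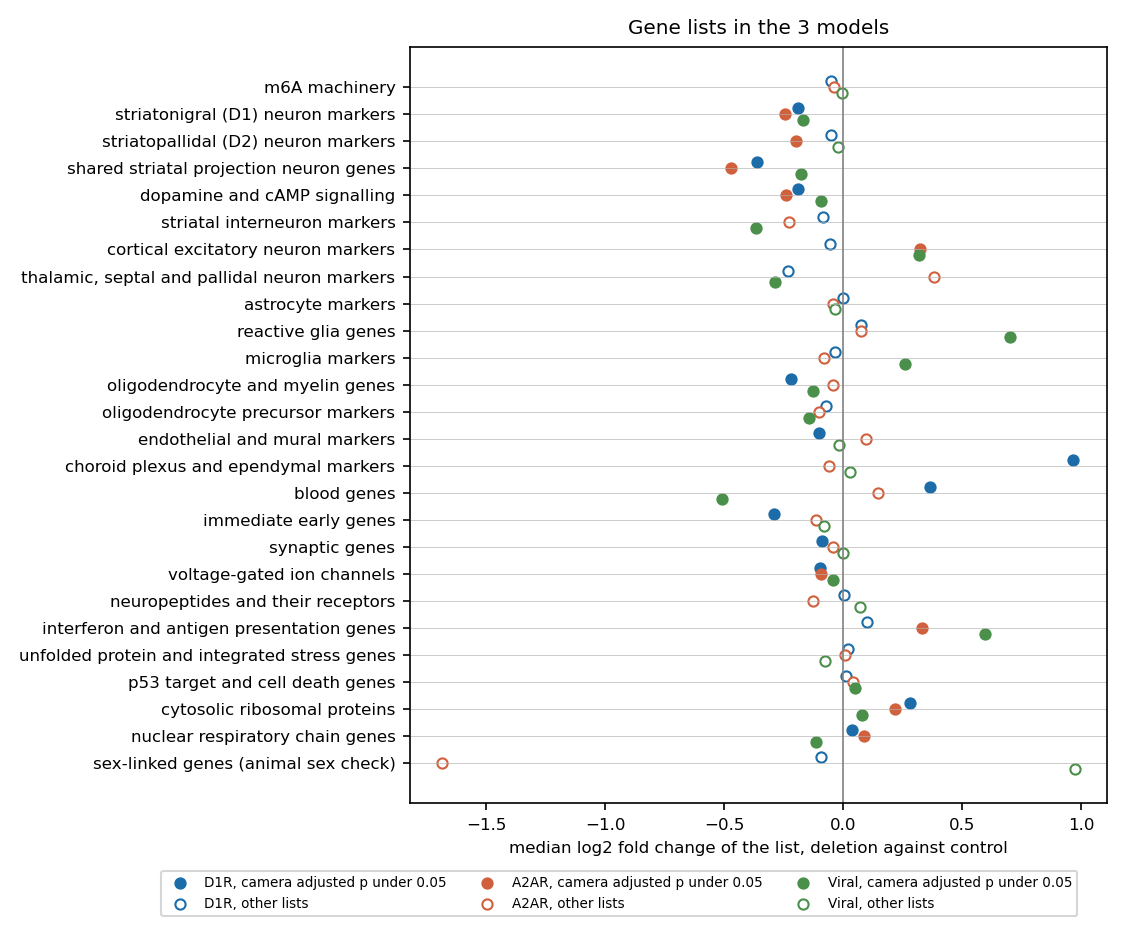
Median log2 fold change, deletion against control (x axis), of each of the 26 tested gene lists (y axis) in the 3 models; each point is 1 list in 1 model, filled where the camera adjusted p at the preset correlation is under 0.05. Shared projection neuron genes lie at −0.36, −0.47 and −0.18 in D1R, A2AR and Viral, and the reactive glia list lies at 0.70 in Viral.

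Viral deletion in all neurons was compared with the Viral_GFP control to find changes after adult, pan-neuronal loss of Mettl14. Reactive glia, microglia and interferon genes were higher in Viral_Cre at the preset correlation, with medians of 0.70, 0.26 and 0.60 on the log2 scale (adjusted p = 0.472 with an estimated correlation for each). The higher means rest on Viral_Cre 1 and 2, since Viral_Cre 3 lay at 0.12, 0.01 and 0.11 over the control mean. Interneuron markers were lower, with a median of −0.37, and the cholinergic genes Chat and Slc5a7 and the peptide gene Sst were among them. Nuclear respiratory chain genes were lower by a small amount in 68 of 73 members. All 30 shared projection neuron genes had a lower mean, though the list means of the libraries overlap between the groups. Of these lists, only the respiratory chain stayed past the threshold with an estimated correlation, with adjusted p = 0.460 with an estimated correlation for interneuron markers and adjusted p = 0.472 for projection neuron genes.

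Limma called 1 gene higher and 1 lower of 15168, both short RNAs, and 942 genes had an unadjusted p under 0.05. Snord33, a guide RNA for 2′-O-methylation, was listed at 0 in all controls and at 175, 115 and 298 RPKM in Viral_Cre (adjusted p = 0.000632). Mir678 was listed at 296 or more in all controls and at 0 or nearly 0 in Viral_Cre (adjusted p = 0.00548). Both have a whole group at or near 0, which the quantification can also give, so neither call is read as a change in level. The groups did not overlap in 11.4% of genes against 10% by chance. The next smallest p-values, not past the test, were those of Chat, which makes acetylcholine (chromosome 14, 32408203 to 32465909; −0.96 ± 0.13, limma adjusted p = 0.639). Then came Cntf, a glial cytokine (2.06 ± 0.27, adjusted p = 0.639 by limma), and Fabp7, a fatty acid binding protein of radial glia and astrocytes (0.66 ± 0.09, adjusted p = 0.740 by limma). Chat was at 9.06, 10.9 and 12.2 RPKM in Viral_GFP and at 4.79, 5.53 and 5.40 in Viral_Cre.

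Reactive glia genes gave a camera adjusted p of 4.22e-10 (adjusted p = 0.472 with an estimated correlation), with 16 of 17 members higher, 8 at an unadjusted p under 0.05 and 5 that rose when adjusted over the list alone. Gpnmb, a glycoprotein of phagocytes, gave 2.16 ± 0.46, the galectin gene Lgals3 1.44 ± 0.33, the cytokine receptor Osmr 0.61 ± 0.16 and the lysozyme gene Lyz2 1.75 ± 0.48. Microglia markers gave a camera adjusted p of 4.88e-07 (adjusted p = 0.472 with an estimated correlation), with the lysosomal gene Cd68 at 0.78 ± 0.17, the adaptor Tyrobp at 0.64 ± 0.21 and the complement gene C1qc at 0.57 ± 0.19. Interferon and antigen presentation genes gave a camera adjusted p of 1.26e-14 (adjusted p = 0.472 with an estimated correlation), with 28 of 29 higher. The immunoproteasome genes Psmb9 and Psmb8 lay at 1.44 ± 0.36 and 0.94 ± 0.26, Ifitm3 at 0.96 ± 0.22 and Bst2 at 0.96 ± 0.29. The p53 target and cell death list had a median of 0.05 (camera adjusted p = 0.0297, and adjusted p = 0.472 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 0.61 ± 0.15 and the death receptor Fas at 0.77 ± 0.22. The library Viral_Cre 3 differed little from the controls on the glia and interferon lists: its mean over the interferon list was 0.11 above the control mean, against 1.40 and 0.83 in the others, and its mean over the reactive glia list was 0.12 against 1.33 and 1.04.

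Interneuron markers gave a camera adjusted p of 8.77e-08 (adjusted p = 0.460 with an estimated correlation). Of these markers 6 of 15 fell when adjusted over the list alone, among them Sst (−0.64 ± 0.12), Pvalb, a calcium buffer of fast-spiking cells (−1.16 ± 0.23), and Slc5a7, the choline transporter (−0.80 ± 0.16). Shared projection neuron genes had a median of −0.18 (camera adjusted p = 4.69e-08, and adjusted p = 0.472 with an estimated correlation), with Gng7 at −0.26 ± 0.09, Syndig1l at −0.31 ± 0.11 and Ppp1r1b, which encodes DARPP-32, at −0.29 ± 0.11. Projection neuron list means were −0.34, −0.09 and −0.14 in Viral_Cre against −0.05, 0.20 and −0.16 in Viral_GFP, so the groups overlap. D1 markers had a median of −0.17 and dopamine and cAMP genes one of −0.09 (camera adjusted p = 0.00877 and adjusted p = 0.000433, with adjusted p = 0.472 and adjusted p = 0.515 with an estimated correlation), Slc35d3 at −0.35 ± 0.08 and Chrm4 at −0.17 ± 0.07. Nuclear respiratory chain genes fell, at a median of −0.11, with a camera adjusted p of 1.26e-14 and adjusted p = 0.0192 with an estimated correlation, which keeps the call, and fry gave an adjusted p of 0.0124. The correlation estimated for this list in Viral was 0.00389, so this setting allowed for no more correlation than the preset 0.01. In D1R and A2AR the estimates for the list were 0.205 and 0.390. Ndufs8 of complex I gave −0.27 ± 0.06, Cox5b and Cox7b of complex IV −0.29 ± 0.07 and −0.26 ± 0.06 and Ndufa2 −0.26 ± 0.07. Of the respiratory chain genes 0 of the 73 passed limma over all genes or adjusted over the list alone, with 20 lower at an unadjusted p under 0.05.

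Other lists at the preset correlation included oligodendrocyte and myelin genes, lower with a median of −0.13 (camera adjusted p = 2.93e-05, and adjusted p = 0.472 with an estimated correlation), with Ugt8a at −0.38 ± 0.07 and Mog at −0.33 ± 0.12. Precursor markers (median −0.14, Neu4 at −0.36 ± 0.15), thalamic, septal and pallidal markers (−0.29, Ramp3 at −0.72 ± 0.21), blood genes (−0.51, Hba-a1 at −1.18 ± 0.28) and ion channels (−0.04, Kcnc1 at −0.32 ± 0.12) had camera directions downwards with adjusted p-values from 0.0103 to 0.0406. The blood list had a mean of −0.07 with 2 of 6 members higher and overlapping groups, so its median is not a shift of the whole list. The ion channel list had a camera adjusted p of 0.0584 with the trend on gene span removed. With an estimated correlation these 4 lists had adjusted p = 0.460, adjusted p = 0.472, adjusted p = 0.472 and adjusted p = 0.567. Cortical excitatory neuron markers were higher in all 13 members, with a median of 0.32 (camera adjusted p = 0.00155, and adjusted p = 0.472 with an estimated correlation), with Neurod2 at 0.70 ± 0.51. The cortical list means of the 3 control libraries ranged from −0.43 to 0.42. Ribosomal proteins had a median of 0.08 and a mean of 0.0019 (camera adjusted p = 4.69e-06, and adjusted p = 0.472 with an estimated correlation). Rpl32 lay at 0.32 ± 0.08 and Rpl30, listed at 0.000271, 0.713 and 1.04 RPKM in Viral_Cre against at least 2.60 in the controls, at −1.99 ± 0.44. Lists not past the threshold had camera adjusted p-values between 0.116 and 0.921. Sex-linked genes had a median of 0.98, D2 markers −0.02, immediate early genes −0.08, unfolded protein genes −0.07, astrocyte markers −0.04 and choroid plexus markers 0.03. Camera's direction differed from the sign of the median for neuropeptides (downwards, 0.07) and endothelial markers (upwards, −0.02), and the m6A machinery and synaptic medians were below 0.01 in size with such a difference too.

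The 18-library limma fit called 8 genes in Viral, 0 of which the fit of 6 libraries called, and made 51 false calls in simulated Viral data with planted changes. Higher were C3, the central complement component (3.23 ± 0.36), Cst7, a cysteine protease inhibitor of activated microglia (2.25 ± 0.38), Gpnmb (2.16 ± 0.33), the glucan receptor Clec7a (1.52 ± 0.24), Socs3, an inhibitor of cytokine signalling (1.51 ± 0.24), and the proteoglycan gene Srgn (0.64 ± 0.09). Lower were Tacr1, the substance P receptor (−0.89 ± 0.13), and Slc5a7. Adjusted p-values of these 8 genes in that fit were between 0.00252 and 0.0480. C3 (chromosome 17, 57203967 to 57228136) was at 1.59, 1.53 and 1.22 RPKM in Viral_GFP and at 36.4, 20.7 and 7.23 in Viral_Cre. Without Viral_Cre 3, 14 genes were called in the fit of the remaining 5 libraries, C3, Gpnmb and Lyz2 among them.

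**Figure D3:**
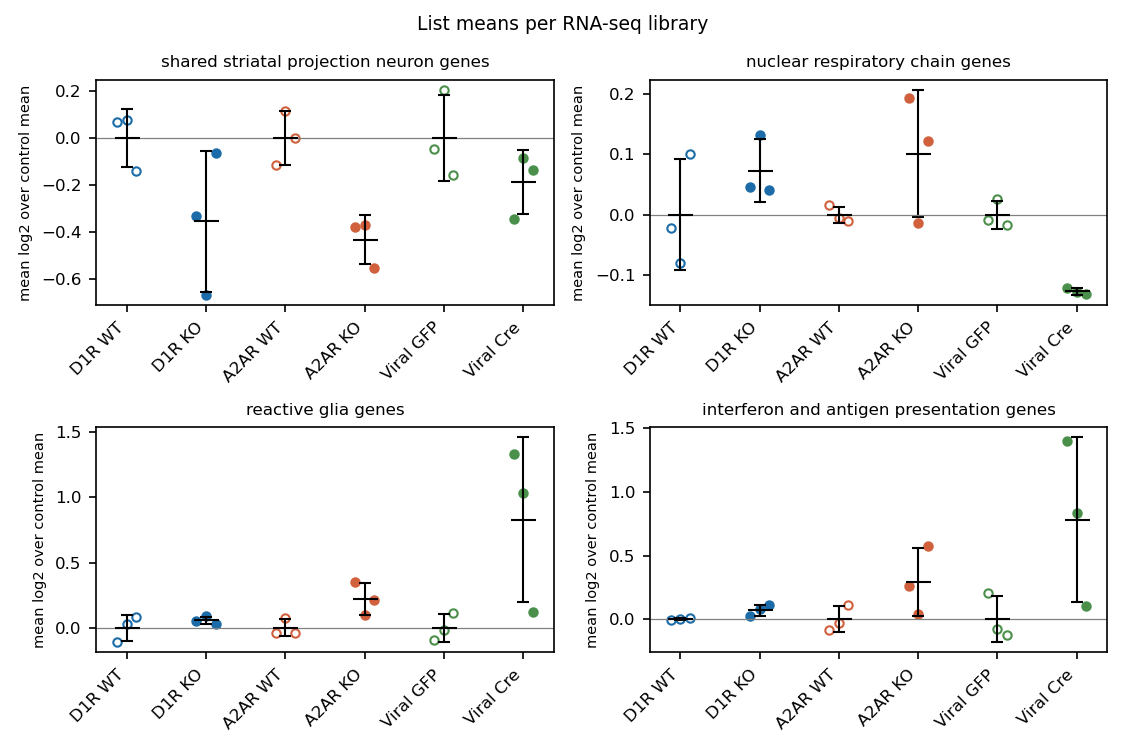
Mean log2 expression of 4 gene lists relative to the control mean of the model (y axis) in each RNA-seq library; each point is 1 library, open for control and filled for deletion, and bars give the mean ± SD of 3 libraries. Viral_Cre libraries lie at 1.40, 0.83 and 0.11 for the interferon list and at −0.12, −0.13 and −0.13 for the respiratory chain list.

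Fold changes of D1R and A2AR went together more than those of other pairs. Their Spearman correlation across 14549 genes was 0.353, against 0.152 for D1R and Viral and 0.188 for A2AR and Viral. Pearson's r was 0.292, 0.120 and 0.230 in the same order, so the lead over A2AR and Viral is smaller by that measure. The differences between pairs were not tested. Genes are not independent replicates, and the 3 models have separate controls. At an unadjusted p under 0.05 in both, D1R and A2AR shared 191 higher genes where 34.1 were expected from independent lists, and 159 lower genes where 39.8 were expected. Libraries regrouped without regard to deletion reached a Spearman correlation of 0.326, against 0.354 for the real groups over the same 14518 genes. Independent lists are therefore a low bar for this overlap. The calls of the fits of 6 libraries shared 0 genes between any 2 models. In the 18-library fit, D1R and A2AR shared 4 genes as higher, Col20a1, Fst and Vsig2 among them (0.0616 expected, one-sided Fisher exact p = 1.96e-07). They shared Pcdhga9 as lower (one-sided Fisher exact p = 0.00422). Both call lists judge a gene by its spread over the same 18 libraries, so a gene with little spread is favoured in both. Fisher's test assumes independent lists, so no conclusion on shared genes is drawn from these p-values. D1R and Viral shared 56 higher genes at an unadjusted p under 0.05 where 21.6 were expected and 32 lower where 27.0 were expected, and A2AR and Viral shared 52 and 51 where 18.8 and 22.6 were expected.

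No gene passed the test of a difference between models. Limma called 0 of 14533 genes for D1R against A2AR (584 at an unadjusted p under 0.05), 0 for D1R against Viral (1068) and 0 for A2AR against Viral (770), with smallest adjusted p-values of 0.126, 0.0559 and 0.0890. A list past the threshold in 1 model and not in another is therefore not shown to differ between them. Of 78 differences in list means between models, 2 had an exact permutation p under 0.05, both for nuclear respiratory chain genes, where about 4 would be expected by chance. The respiratory chain mean was 0.06 in D1R and −0.13 in Viral over shared genes, a difference of 0.189 (exact permutation p = 0.01, two-sided, adjusted 0.780), and 0.10 in A2AR against −0.13, a difference of 0.228 (exact permutation p = 0.0200, adjusted 0.780).

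The m6A peak lists of deletion and control were similar in size in all 3 models. D1R_WT had 33551 peaks in 11105 genes and D1R_KO 33854 in 11315, A2AR_WT 29645 in 10101 and A2AR_KO 29395 in 10058, and Viral_GFP 26731 in 9484 and Viral_Cre 25864 in 9252. In D1R, 84.0% of control peaks (95% interval 83.6 to 84.4) were overlapped by a deletion peak and 83.1% of deletion peaks (82.7 to 83.5) by a control peak. The shares were 82.1% (81.7 to 82.6) and 83.7% (83.3 to 84.1) in A2AR and 81.7% (81.2 to 82.2) and 83.2% (82.8 to 83.7) in Viral. Peaks without an overlap had lower scores by the authors' measure, a median of 1.70 against 2.41 in D1R_WT, 1.19 against 1.84 in A2AR_WT and 1.28 against 1.97 in Viral_GFP. Over overlapping pairs the score was lower in the deletion list by a little: the median log2 difference was −0.027 in D1R, −0.017 in A2AR and −0.051 in Viral, with 52.4%, 52.4% and 56.7% of pairs lower. The authors' deposited ratio column in D1R has medians of 0.136 for control over deletion in the control list and 0.0789 for deletion over control in the deletion list, so each list favours its own group.

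**Figure D4:**
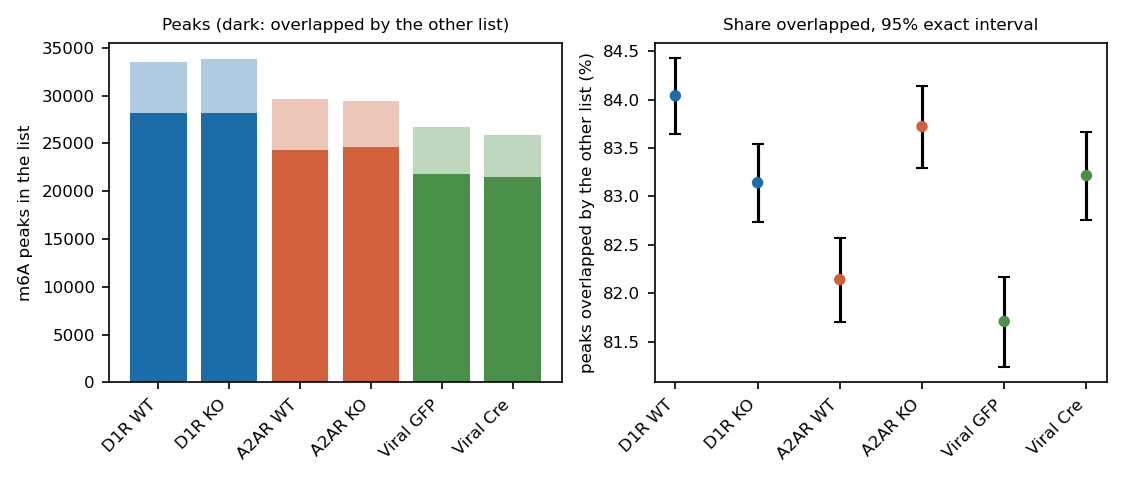
Left, the number of m6A peaks per group (y axis), with peaks overlapped by the other group's list in dark; right, the share of peaks overlapped in percent (y axis not starting at 0) with its exact 95% interval. The shares lie between 81.7% in Viral_GFP and 84.0% in D1R_WT.

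In A2AR and Viral, where every library has a score per peak, limma called 0 of 34430 and 0 of 31072 peaks. At an unadjusted p under 0.05 there were 1941 peaks in A2AR, 1148 lower and 793 higher, and 1915 in Viral, 1198 lower and 717 higher. The median difference was −0.0264 in A2AR and −0.0628 in Viral with the control list taken first, and −0.0018 and −0.0414 with the deletion list first, so the A2AR value depends on the list. The test recovered between 0 and 38 of 100 simulated shifts of −1 or −2, so single peaks were not resolved. Shifts as small as these medians were not simulated. The smallest p-values in A2AR belonged to peaks of the polarity gene Mpp5 (5′ UTR, transcript positions 58 to 213, score 3.62 in control and 2.19 in deletion, −1.43 ± 0.22) and the coactivator Ncoa3 (3′ UTR, 6228 to 6330, −1.46 ± 0.23), with limma adjusted p-values of 0.882. In Viral they belonged to Fbxw4 (CDS, 361 to 530, 1.66 ± 0.26) and the histone gene H2afx (3′ UTR, 1011 to 1200, −1.66 ± 0.27), with limma adjusted p-values of 0.795. Mettl14 carried peaks in both D1R lists at 1326 to 1482 (3.22 in control and 3.35 in deletion) and 8 to 164 (2.07 and 2.30). In A2AR Mettl14 had peaks at 21 to 120 (0.54 ± 0.27) and 1391 to 1507 (0.47 ± 0.33) in the deletion list only, and in Viral at 291 to 410 (0.41 ± 0.41) in the control list.

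Among peaks found in the control list alone, the highest in D1R lay in 1810013L24Rik (1 to 135, score 5.95), Ankrd33b (1314 to 1471, 5.75), Syncrip, an RNA-binding protein gene (1 to 101, 5.61), Cd274, which encodes PD-L1 (2475 to 2625, 5.47), and Gabra4, a GABA receptor subunit (1 to 134, 5.35). In the D1R deletion list alone they lay in Nptn, a synaptic adhesion gene (8 to 142, 6.43), Naa30 (159 to 417, 5.98), Ppp2cb (1 to 100, 5.79), Calb1, a calcium buffer (2565 to 2717, 5.78), and Nanos1 (6 to 177, 5.66). In A2AR and Viral the scores of such peaks were often similar in both groups. The A2AR control-only peaks were 2 in the protocadherin gene Pcdhga5 (1711 to 1840, 3.95 in control and 3.36 in deletion, and 1901 to 2010, 3.94 and 3.73). The others lay in Msl1 (530 to 674, 3.94 and 3.94), Basp1 (641 to 760, 3.84 and 3.98) and Rnf11 (748 to 886, 3.81 and 3.56). The A2AR deletion-only peaks lay in the vesicle protein gene Sv2a (714 to 817, 4.53 in control and 3.93 in deletion), Pitpna (14 to 191, 3.85 and 3.89), Rnf146 (1502 to 1608, 3.55 and 3.79), Efr3b (2292 to 2458, 3.70 and 3.63) and Coa5 (51 to 218, 3.23 and 3.54). In Viral, 4 of the 5 highest control-only peaks lay in protocadherin genes, Pcdhga3 (1881 to 2040, 4.39 and 4.12), Pcdhga5 (1701 to 1920, 4.32 and 4.11), Pcdhga2 (1771 to 1870, 3.84 and 3.72) and Pcdhga11 (2081 to 2180, 3.79 and 3.48), whose transcripts share their 3′ exons. The other lay in Ulk2 (3762 to 3862, 3.81 and 3.65). The Viral deletion-only peaks lay in Timp2 (71 to 258, 2.76 in control and 3.93 in deletion), Dusp8 (1723 to 1892, 2.47 and 3.92), Ttl (1543 to 1817, 3.86 and 3.73), Kif5c (1 to 138, 2.88 and 3.72) and a transcript without a gene name (1434 to 1545, 3.99 and 3.94).

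Over all tested genes, those with an m6A peak in the control list had lower expression fold changes than those without one in each model, but in Viral this depended on expression level. The difference in mean log2 fold change was −0.0434 in D1R (10996 genes with and 4028 without a peak), −0.0745 in A2AR (10010 and 5066) and −0.0557 in Viral (9402 and 5766). The permutation p was 1e-05 in each, the smallest that 100000 resamples can give (adjusted 2e-05 over 9 tests), with genes and not animals as the units. Genes without peaks also had lower expression, with median RPKM of 1.76, 2.09 and 2.38 against 13.0, 14.1 and 15.0. Their fold changes spread more, with SDs of 0.707, 0.724 and 0.734 against 0.199, 0.183 and 0.159. Short RNAs, some listed at 0 in a whole group, were not left out here, so their part in these differences was not tested. Genes were matched on expression level only and not on gene span. Fold changes correlated with span (Spearman −0.208 in D1R, −0.253 in A2AR and −0.0123 in Viral), and the part of that trend in these differences was not tested. In D1R the difference was −0.109 among genes with a mean RPKM of at least 5 and −0.0968 among genes matched on expression (permutation p = 1e-05 for each), and without D1R_KO 1 it was −0.0259 (permutation p = 0.00200). In A2AR it was −0.0393 (permutation p = 0.0001) without A2AR_KO 3. In Viral the difference was 0.0170 (permutation p = 0.216) among genes with a mean RPKM of at least 5 and −0.00898 (permutation p = 0.638) among genes matched on expression, and −0.0839 (permutation p = 0.0001) without Viral_Cre 3. Genes that lost all their control peaks differed from genes that kept one by −0.0461 in D1R (629 and 10367 genes, permutation p = 1e-05), by 0.0058 in A2AR (815 and 9195, p = 0.383 by permutation) and by −0.0077 in Viral (966 and 8436, p = 0.155 by permutation). At a mean RPKM of at least 5 the D1R value was 0.0167 (permutation p = 0.207), with the sign turned, and the A2AR value 0.0424 (permutation p = 1e-05).

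Across genes, the change in the highest peak was weakly correlated with the change in mRNA. Pearson's r was 0.0243 in D1R (10526 genes, permutation p = 0.0122, adjusted 0.0183), 0.0520 in A2AR (9404 genes, permutation p = 1e-05) and −0.0093 in Viral (8658 genes, permutation p = 0.387). Spearman's rho was 0.0260, 0.0263 and −0.0314 (permutation p = 0.00786, 0.0105 and 0.00361). At a mean RPKM of at least 5 the D1R correlation was 0.0172 (permutation p = 0.109). In all 3 models the RNA-seq libraries are also the input of the m6A score, so the m6A and expression changes are not independent. The sign of r turned in D1R and A2AR when the mean of a gene's peaks replaced the highest peak. With the mean peak r was −0.0285 in D1R (permutation p = 0.00338), −0.0133 in A2AR (permutation p = 0.196) and −0.0448 in Viral (permutation p = 2e-05). The D1R correlation thus passed the test in opposite directions, so its direction rests on how peaks are summarized.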

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

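All tests in this part were chosen after the results were seen, apart from the splits of the m6A and expression comparisons.

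For nuclear respiratory chain genes the mean log2 fold change was 0.06 in D1R against −0.13 in Viral, a difference of 0.189 (exact permutation p = 0.01), and 0.10 in A2AR against −0.13 in Viral, a difference of 0.228 (exact permutation p = 0.0200). They are listed because the difference between groups passed its own test at an unadjusted p under 0.05, as 2 of 78 list differences did where about 4 are expected by chance (adjusted 0.780), a rule adopted after camera on the same contrasts gave 25 list calls at the preset correlation and 0 with an estimated one. With the trend of expression on gene span removed the differences were 0.161 and 0.189 (exact permutation p = 0.015 for each), which argues against that trend as the whole cause, and without both D1R replicate 1 libraries the D1R difference was 0.20 (exact permutation p = 0.0167 over 120 regroupings), which argues against their batch. The D1R difference misses an exact permutation p under 0.05 (0.0550) without any 1 of D1R_WT 1, D1R_WT 2, D1R_KO 2 and D1R_KO 3. Chance among the 78 differences stays open, and so do the separate normalization of the tables and a response that depends on which neurons lose Mettl14, which was not tested.

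D1R and A2AR fold changes were correlated over 14518 genes (Spearman 0.354). Of 100 regroupings of the libraries 1, the real one, gave a value as large, the next being 0.326. This is the smallest count possible, but the next value is close and the pair was singled out as the highest of 3. A chance arrangement of these libraries is therefore not excluded. With the first replicates of D1R left out the correlation was 0.339 against 0.271 for the highest of the other regroupings, 30 in all, which argues against that batch. With the span trend removed the correlation was 0.321, which argues against that trend as the whole of the correlation. The highest other regrouping then gave 0.317, too close to tie the rest to the deletion. More neighbouring tissue in both deletion dissections cannot be told apart either, since cortical markers had a mean of 0.0041 in D1R and of 0.30 in A2AR, with overlapping groups in both. A response to Mettl14 loss common to both neuron types may be part of the pattern and stays a hypothesis.

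Viral glia and interferon genes were high in some Viral_Cre libraries: on the interferon list the 3 libraries lay at 1.40, 0.83 and 0.11, on reactive glia at 1.33, 1.04 and 0.12 and on microglia markers at 0.56, 0.38 and 0.01. Of the 3, 1 (Viral_Cre 3) lay within 2 SD of the Viral_GFP mean on the interferon list, a count taken from the values that prompted it, so a response of single libraries and a uniform one cannot be told apart. Differences in injection or spread of the virus, or in tissue response, may underlie this, and no value used here tells them from an effect of Mettl14 loss that varies between samples. On the respiratory chain list the same libraries lay at −0.12, −0.13 and −0.13, so Viral_Cre 3 stood with its group there.

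Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05, so only the real value and the highest other are given. For the fit of 6 libraries these were 5 and 5 calls in D1R, 1 and 5 in A2AR and 2 and 5 in Viral, and 2, 9 and 7 of the 10 splits gave as many as the real one. For the 18-library fit they were 160 and 3, 10 and 1, and 8 and 1, and with short RNAs left out 29 and 1, 5 and 2, and 0 and 4. For lists past the camera threshold they were 12 and 10 in D1R, 9 and 15 in A2AR and 16 and 16 in Viral, so other splits of the A2AR and Viral libraries gave as many lists. For changed m6A peaks they were 0 and 0 in both A2AR and Viral, and for the size of the median shift 0.0264 and 0.0301 in A2AR and 0.0628 and 0.0739 in Viral. With the deletion list taken first the A2AR median was −0.0018, so that shift depends on the list.

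For m6A and expression, the sizes of the real value and of the highest other split in D1R were 0.0434 and 0.0334 (peak against none), 0.0461 and 0.0410 (lost against kept) and 0.0243 and 0.0309 (correlation). In A2AR they were 0.0745 and 0.0600, 0.0058 and 0.0254, and 0.0520 and 0.0605, and in Viral 0.0557 and 0.0612, 0.0077 and 0.0316, and 0.0093 and 0.0333.

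For differences between models the real grouping called 0 genes in each pair, so all 100 of 100 regroupings gave as many, and the highest other gave 16 in D1R against A2AR, 70 in D1R against Viral and 2 in A2AR against Viral. A regrouping with 70 calls points to a structure among the libraries that the groups do not describe, or to the fit itself, which made up to 69 false calls within a model in simulated data, and neither was tested.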

How the results depend on the processing

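All settings named here as added (robust eBayes, short RNAs left out, the Y-linked covariate, the span trend, the first D1R replicates, median centring of lists and m6A scores, all settings of the respiratory chain differences, single libraries left out for lists, m6A peaks and m6A-and-expression, and the overlaps) were chosen after the results were seen, and the others before. Where a value moved, the cause was not tested unless stated. No called gene or list turned direction in any setting. Of 2926 gene-by-setting values 2815 kept their side of the threshold, 35 lost the call, 76 gained it and 0 reversed with a call. Of 988 list-by-setting values these counts were 825, 121, 42 and 0. For lists with an estimated correlation the direction was taken from the main test, so it could not turn. Among the values that kept their side, signs turned in 2 uncalled gene values (Mettl14 at 0.01 without A2AR_WT replicate 1 and at 0.00 without Viral_Cre replicate 3) and in 63 uncalled list values. For m6A and expression they turned in 3 of 75 with neither value past the test. Pseudocounts, filters, quantile and median scaling and the span trend kept the counts of called genes within each model within 1.5 times.

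Called genes in D1R (5) were 160 in the 18-library fit, 29 with robust eBayes, 29 with short RNAs left out, 1 with the Y-linked covariate, 32 with a term for the batch of replicate 1, 93 with that term and no short RNAs. They numbered between 2 (without D1R_WT 1, and 3 without D1R_KO 1) and 8 (without D1R_KO 3) with 1 library left out. A2AR (1) gave 10 in the 18-library fit, 2 without trend, 9 robust and 5 with short RNAs left out, and 2 to 14 with 1 library left out (14 without A2AR_WT 3, 4 without A2AR_WT 1 or 2, and 2, 3 and 3 without A2AR_KO 1, 2 and 3). Viral (2) gave 8 in the 18-library fit, 1 robust, 0 with short RNAs left out (limma, 961 at an unadjusted p under 0.05). With 1 library left out it gave 2 to 14: 8, 9 and 7 without Viral_GFP 1, 2 and 3, and 6, 2 and 14 without Viral_Cre 1, 2 and 3. Tgm7 was called in 14 of 21 settings and Lime1 in 12 of 22, and both calls were lost with the Y-linked covariate and without both replicate 1 libraries. In simulated data the 18-library fit made 69, 38 and 51 false calls in D1R, A2AR and Viral, against 4, 5 and 5 for the fit of 6 libraries.

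By the rule that every pair correlate over 0.1, replicate numbers were not taken as pairs. The correlations of same-numbered deviations were 0.361, 0.0385 and 0.121 in D1R, 0.00243, 0.0303 and −0.0578 in A2AR and 0.0550, −0.0284 and 0.0142 in Viral, and 3, 2 and 3 of 6 libraries correlated best with their own number. With short RNAs left out they were 0.676, 0.0670 and 0.211 in D1R, 0.0799, −0.0172 and 0.0435 in A2AR and 0.138, −0.0102 and 0.0777 in Viral, with 3, 3 and 4 of 6. In D1R the replicate 1 libraries thus share a structure, and same-numbered libraries also agree in sex-linked genes, a hint from the data and not the design. With the replicate block, 1 gene was called in D1R and 1 in Viral, and 1 for the difference of D1R and Viral, and no other count of called genes moved by more than 1.5 times. D1R genes at an unadjusted limma p under 0.05 numbered 1632 without the block and 2477 with it, so a pairing in D1R is not excluded. The block ended the Tgm7 and Lime1 calls.

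Gene lists past the threshold (12, 9 and 16) became 0, 0 and 1 with an estimated correlation and 0, 0 and 1 with fry, the 1 being the respiratory chain list in Viral. The correlation estimated for that list in Viral was 0.00389, under the preset 0.01. Camera's preset correlation assumes nearly independent genes. Fold change and gene span had a Spearman correlation of −0.208 in D1R, −0.253 in A2AR and −0.0123 in Viral, and with the span trend removed the lists numbered 8, 12 and 15. The blood, synaptic, ion channel and respiratory chain lists lost the call in D1R and the ion channel list in Viral, and the ribosomal list kept it in D1R. With 1 library left out D1R gave 6 (without D1R_WT 2) to 12 and A2AR 10 to 14 (without A2AR_KO 2). Differences between models (0 each) gave 4 genes for D1R and Viral with a pseudocount of 1, 3 with median centring, and 1 for A2AR and Viral with median centring. With 1 library left out they gave 0 to 2 for D1R and A2AR (2 without D1R_KO 2), 0 to 6 for D1R and Viral (6 without Viral_GFP 3, and 3 without Viral_Cre 3) and 0 to 6 for A2AR and Viral (6 without Viral_Cre 3). Shared genes (0) became 4 higher and 1 lower for D1R and A2AR in the 18-library fit, and at an unadjusted p under 0.05 191 and 159 for D1R and A2AR, 56 and 32 for D1R and Viral and 52 and 51 for A2AR and Viral. The respiratory chain difference of D1R and Viral ranged from 0.161 to 0.233 with 1 library left out and had an exact permutation p of 0.0550 without D1R_WT 1, D1R_WT 2, D1R_KO 2 or D1R_KO 3. That of A2AR and Viral kept an exact p under 0.05 in all 16 settings (0.181 to 0.285).

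With an overlap of 50% of both peaks, the shares of control and deletion peaks overlapped were 80.4% and 79.6% in D1R, 73.3% and 74.0% in A2AR and 72.4% and 74.8% in Viral, a stricter rule by construction, and the median pair difference in Viral was −0.0606. With only peaks at or above the joint median score they were 79.0% and 80.0%, 83.1% and 84.4%, and 82.4% and 85.2%, and with equal numbers of top peaks the moved shares were 83.5% (D1R control), 82.7% (A2AR control), 83.2% (Viral control) and 82.0% (Viral deletion). Changed m6A peaks in A2AR (0) were 0 to 5 with 1 library left out (5 without A2AR_WT 3).

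For m6A and expression, a mean RPKM of at least 5 gave 0.0167 for D1R lost against kept (sign turned), 0.0172 for the D1R correlation, 0.0424 for A2AR lost against kept and 0.0170 for Viral peak against none (sign turned). Matching on expression gave −0.00898 for Viral peak against none, and the 50% overlap 0.0134 for A2AR lost against kept. The mean of a gene's peaks gave correlations of −0.0285 in D1R and −0.0133 in A2AR (both signs turned) and −0.0448 in Viral (permutation p = 0.00338, 0.196 and 2e-05). With 1 library left out the D1R correlation ranged from 0.0121 to 0.0309 (past the test except without D1R_WT 1 or D1R_KO 2), A2AR lost against kept from −0.00136 to 0.0182 (past it without A2AR_KO 2) and Viral lost against kept from −0.0193 to 0.000643 (past it without Viral_Cre 1 or Viral_GFP 2). The Viral correlation ranged from −0.0190 to 0.00233, never past the test, and the difference of peak against none reached −0.0839 without Viral_Cre 3, −0.0259 without D1R_KO 1 and −0.0393 without A2AR_KO 3. Depth is unknown, so how far counting error limits low genes and short RNAs cannot be given.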

Other observations

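All tests in this part other than the limma test of m6A peaks were chosen after the results were seen, on gene lists fixed beforehand, and the peaks of single genes below were singled out after their values were seen.

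The m6A scores of striatopallidal transcripts were lower in A2AR_KO at several peaks. In Adora2a, the adenosine A2a receptor gene, the coding-sequence peak at transcript positions 965 to 1209 was at 1.80 ± 0.16 in A2AR_WT and 0.46 ± 0.30 in A2AR_KO (SD, n = 3 per group), a difference of −1.34 (limma, adjusted p = 0.882). The peak at 1512 to 1700 gave −0.77. The Drd2 peak at the stop codon (1361 to 1540) gave −1.24. In Viral the same Adora2a region (965 to 1208) gave −0.25 and the Drd2 stop codon peak −0.36. Other peaks were higher or hardly moved: the Adora2a 5′ UTR peak (206 to 372) gave 1.01 in A2AR, the Drd2 coding-sequence peak (900 to 1154) gave 0.03, and the start of the orphan receptor gene Gpr6 (1 to 100) gave 1.46 in A2AR and 1.12 in Viral. Over the 31 peaks of D2 markers the median was −0.29 in A2AR (camera adjusted p = 0.0729 over the lists, and adjusted p = 0.431 with an estimated correlation).

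Peaks of interferon and antigen presentation genes had a median score change of 0.21 in Viral (camera adjusted p = 0.0117, and adjusted p = 0.950 with an estimated correlation), in the model in which their expression was also higher. The sex-linked list, with 20 peaks in 4 genes, passed there too, at a larger median of 0.58 (camera adjusted p = 0.0202, and adjusted p = 0.950 with an estimated correlation). The RNA-seq libraries are the input of the score, and whether input level underlies either value was not tested. In D1R, with 1 m6A library per group, the median over voltage-gated ion channel genes was −0.11, at the 1.98th percentile of 10000 random lists matched on expression, and those over D1 and D2 markers were −0.24 and −0.14, at the 5.05th and 9.84th percentiles, as a description of these libraries. The ion channel percentile was the lowest of all D1R lists, and the highest was that of neuropeptides and their receptors (median 0.16, 95.33rd percentile). Peaks lay mostly in coding sequence, 46.5% in A2AR_WT, 47.5% in A2AR_KO, 47.4% in Viral_GFP and 48.1% in Viral_Cre, and in the 3′ UTR, 26.7%, 26.2%, 27.1% and 26.2%. The authors' lists mark a GGACU motif in 29.5% of overlapped and 21.3% of other A2AR_WT peaks and in 29.1% and 22.2% of Viral_GFP peaks.

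Of 3 hypotheses tested here, unadjusted, 2 gave a p under 0.05. The first was that transcripts of the targeted neuron lose m6A: peaks of D2 minus those of D1 markers gave −0.38 in A2AR and 0.05 in Viral, a difference of −0.43 (exact permutation p = 0.01). Because the peaks of Adora2a, Drd2 and Gpr6 had prompted it, the test was repeated without these genes and gave −0.42 in A2AR and 0.03 in Viral, a difference of −0.45 (exact permutation p = 0.0250). The list median of D2 markers had also been seen, so neither p is independent of what prompted the test, and the hypothesis stays open beside a lower share of targeted RNA in the input. The second was that each model lowers the markers of its own neuron: D1 minus D2 marker expression was −0.22 in D1R and 0.06 in A2AR, a difference of −0.28 (exact permutation p = 0.0300). The A2AR value rests on list means (−0.23 for D1 and −0.29 for D2 markers), while the medians go the other way (−0.25 and −0.20), and the list changes had been seen before. Taken alone, neither D1 markers (a difference between D1R and A2AR of −0.06, exact permutation p = 0.800) nor D2 markers (0.22, exact permutation p = 0.265) passed, so no loss of a model's own markers is shown. The third was uneven dissection: over the 18 libraries with group means removed, projection neuron and cortical scores had a Pearson r of −0.591 (permutation p = 0.0622) and a Spearman rho of −0.546 (permutation p = 0.0845), and r was −0.395 without the 2 libraries farthest from the median. It did not pass, and dissection cannot be told apart from the groups at this size.

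The 2 first D1R replicates share a very high level of the short RNA Mir6236, 260583 RPKM in D1R_WT 1 and 210032 in D1R_KO 1, against 12990 to 19139 in the other 4 D1R libraries.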
